A study of Mus musculus with 11 samples.

How the data were processed

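The values are raw read counts per gene, whole numbers as deposited, in 1 table of 22369 mouse Ensembl gene IDs by 11 libraries. Per the submitters' processing notes, TopHat 1.4.0 and Bowtie 0.12.7 were used, and the genome builds named are mm9 and hg19. Per the deposited file's name, the table holds protein-coding genes of Ensembl release 66 and names hg19, although every ID is a mouse ID. The tool that counted reads, strand and the handling of reads with several matches are not given in the sources used here. Per the labels' protocols, total RNA was isolated with the RNeasy kit, and libraries were made with the TruSeq RNA kit. The table held 0 lines that were not genes and 0 columns without a label. Symbols were found for 20777 IDs, and the other 1592 held 0.401% of counts, of which 133 were tested under their ID. Chromosome and gene order came from GENCODE vM21 on GRCm38, a later build than mm9, so only chromosome names and neighbours were used. Reporter integration sites were not used here.

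Counts were analysed in R 4.3.3 with edgeR 4.0.16, on TMM library sizes (factors 0.971 to 1.04), for 12479 genes with a mean of at least 1 CPM. Variable genes came from an intercept-only negative binomial fit with trended dispersion and a chi-square goodness-of-fit test on 10 degrees of freedom. Each clone was compared with the other 10 by the edgeR quasi-likelihood test, with Benjamini-Hochberg adjustment over 137269 pairs. Standard errors (SE) of its log2 fold changes were derived from the fold change and the F statistic. They restate the test result and hold no spread within a clone. The common coefficient of variation was 24.8%. With 1 library per clone, biological and library variation of a clone cannot be separated. Chromosome shifts were medians over genes of log2(CPM + 1) against the median clone, for 10274 genes with a mean of at least 5 CPM, tested against 10000 random gene sets. A call also needed a shift of at least 0.2. Segments were runs of windows of 25 genes beyond 0.36, a threshold from 100 permutations of gene order. List enrichment used Fisher's exact test on lists with at least 5 tested members, and score correlations used 100000 permutations. The exact test treats the genes of a list as independent, which they are not. DESeq2 1.42.0 served for alternatives, with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 for the rest. The tests, lists and alternatives were chosen before the data were examined, except the segment scan, the analyses without segment genes, and the tests of explanations in the closing part, which were added later.

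Data for the clone and variable-gene tests were simulated with each gene exactly on the dispersion trend, so these rates need not hold for real genes. With 50 changed genes per fold, the clone test recovered 0, 7, 35 and 43 at 1.5, 2, 4 and 8-fold, and the variable-gene test 0, 2, 33 and 42. Of the calls, 4 of 89 by the clone test were on unchanged pairs of gene and clone, and 11 of 88 by the variable-gene test on unchanged genes. The chromosome test found 2 of 2 simulated shifts and 0 others, reading 0.48 for a 1.5-fold shift and -0.88 for a 0.5-fold one. The segment scan found 2 of 2 and 0 others, with ends at most 3 genes off. The correlation test called 198 of 200 strongly linked and 10 of 200 unlinked pairs. Weaker links were not simulated, so its recovery of those is not known. Named genes are the 25 variable genes with the largest SD at a mean of at least 5 CPM, up to 3 genes higher and 3 lower per clone by fold, per list the 3 with the highest CPM and up to 4 called members, the 10 genes with the highest CPM, and Pgk1, Hprt, Pou5f1, Nanog and Sox2. Of 441 genes in 29 lists, 413 were in the table. The mitochondrial-encoded list had 0 of 13 in it and was not analysed here. Results of the other lists are in the report.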

Results

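Messenger RNA was sequenced in 11 clonal lines of mouse embryonic stem cells, 1 library per clone. The parental line, EBRTcH3, makes a tetracycline-controlled transactivator from the ROSA26 locus. Each clone carried multiple barcoded piggyBac reporters with the mouse PGK promoter. It was picked as a single colony from cells sorted for strong eGFP. The cells were grown with leukemia inhibitory factor (LIF) and inhibitors of MEK and of GSK-3, a medium that holds embryonic stem cells in a naive state. The labels place all clones, named here 16 to 26, in 1 group with no treatment to compare, so the comparisons are of the clones with each other. Counts in genes totalled 10846005 in clone 16 to 16868500 in clone 23 (median 14378599), and 15910 to 16634 genes had at least 1 count. All levels are CPM on TMM-scaled library sizes, given as mean ± SD over the 11 clones unless stated. The floor of detection, 3 counts, corresponded to 0.178 to 0.277 CPM.

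Transcripts of the pluripotency network were abundant in every clone. Pou5f1 stood at 863 ± 72.0 CPM, Sox2 at 845 ± 84.8 and Nanog at 751 ± 90.04 (n = 11), and the naive-state transcription factors Tfcp2l1 and Esrrb at 1971 ± 423 and 1387.5 ± 176. The 22 members of the core and naive pluripotency list summed to 11971 ± 686 CPM. The genes with the highest levels were Eef1a1 (12293 ± 1394 CPM), Eef2 (7198 ± 732), Hsp90ab1 (6915 ± 827) and Fn1 (5324 ± 956), followed by Rpl4, Rack1, Ncl, Nedd4, Slc2a3 and Pkm at 2706 to 3920. Pgk1, whose promoter the reporters carry, stood at 328 ± 54.1 CPM, and Setd5 and Thumpd3 of the construct-related list at 352 ± 18.8 and 64.6 ± 5.47. Of its 3 tested members 0 varied between clones, by the edgeR test used below, at an unadjusted p under 0.05, with the dispersion trend of DESeq2, or adjusted over the list alone. Hprt, the purine salvage enzyme, was at 0 to 0.340 CPM, at or near the floor in all clones.

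Markers of liver, blood and the primitive streak were low. Of the liver list 2 of 10 members and of the blood list 3 of 8 reached a mean of 1 CPM, with Fgg at 2.13 ± 1.44, Apob at 1.29 ± 0.614 and Spi1 at 4.39 ± 1.19 CPM. Of the primitive streak and mesoderm list 3 of 13 members did so (Eomes 10.2 ± 4.07, Kdr 1.24 ± 0.862, Mesp2 1.01 ± 0.461). The liver, blood and primitive streak lists held 0 variable genes in the edgeR test and 0 with the dispersion trend of DESeq2. In each, 1 member had an unadjusted p under 0.05, and the counts adjusted over the list alone were 1, 1 and 0. Of the fibroblast list 7 of 15 members reached 1 CPM, led by Fn1 and Vim (235 ± 57.7), with Pdgfrb at 11.0 ± 4.65 and the variable gene Col1a1 at 1.17 ± 1.29 CPM. In the neural list 3 of 4 tested members varied between clones (3 adjusted over the list alone): the tubulin Tubb3 ranged from 19.2 to 89.6 CPM, the intermediate filament gene Nes from 11.0 to 75.9 with the highest level in clone 19, and Pax6 was at 10.2 CPM in clone 17. Of the 3 variable neural members, 2 lie in chromosome segments that were shifted in at least 1 clone, as do 2 of all 4 tested. Lists with fewer than 5 tested members had no enrichment test.

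The first comparison asked which genes spread more between the clonal lines than other genes of the same abundance. Plagl1, an imprinted zinc finger gene, ranged from 0.567 CPM in clone 24 to 267 CPM in clone 19. Lefty2, which encodes an antagonist of Nodal, stood at 488 CPM in clone 26 and 402 in clone 19 against 11.8 in clone 16, and its neighbour and paralogue Lefty1 spread from 3.40 to 126 CPM. The Wnt target Sp5 was at 41.9 CPM in clone 19 and 22.6 in clone 26 against 0.630 in clone 24, and the cholesterol exporter Abca1 ranged from 7.67 to 210 CPM. The Y-linked genes Ddx3y, Eif2s3y, Uba1y, Uty and Zfy1 were also among the 25 variable genes with the largest spread, as were Spry4 and Etv4 of the MEK/ERK list. The others were Ly6a (0 to 55.5 CPM), Sash3, Pkd2l1, Lrrc15 (1.90 to 107), Nxf3, Nefm (3.12 to 71.5), S100a13, Cited4, Aox3, Tgfbr3, Ido2, Zfp423 and a gene without a symbol, ENSMUSG00000074140. In all, 959 of 12479 tested genes (7.68%) passed the edgeR goodness-of-fit test against the trended dispersion at a Benjamini-Hochberg adjusted p of 0.05. Of these, 314 lay in chromosome segments that were shifted in at least 1 clone, as did 2668 of all 12479 tested genes. In simulated data with known answers 11 of 88 calls by this test were on unchanged genes, above the nominal rate. Each simulated gene lay exactly on the dispersion trend, while real genes can scatter around it. That share therefore does not carry over to the 959 calls. Against counting noise alone 11902 genes passed, and with genes in segments and Y-linked genes left out 615 did.

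Many genes that respond to MEK/ERK signalling were variable between clones in a medium that held a MEK inhibitor. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, was at 4.68 CPM in clone 19 and 21.4 in clone 26 against 51.6 to 134 in the other 9 clones. The ETS factor gene Etv4 followed the same order at the low end, with 6.58 CPM in clone 19, 16.02 in clone 26 and 42.9 to 175 elsewhere, and Spry2 and Spred1 were at 75.1 and 49.0 CPM in clone 19 against means of 153 ± 43.2 and 108 ± 32.9 over all clones. Spry2 is the first gene of a part of chromosome 14 that was lower as a whole in clone 19, by a median of -0.79 on the log2 scale. Of the list, 2 of the 8 variable members and 3 of all 14 tested members lay in shifted segments. The list's most abundant member, Etv5, did not pass the test (582 ± 65.2 CPM), nor did Spred2 (130 ± 14.5). The mean log2 score of the list was -0.97 in clone 19 and -0.60 in clone 26, and between -0.01 and 0.31 in the others. Of 14 tested members 8 were variable (8 adjusted over the list alone), 57.1% against 7.63% of other genes (Fisher's exact test, two-sided, adjusted p = 2.04e-05 over 23 lists; 1.05e-05 to 0.00128 over 15 alternatives). The exact test counts genes as independent, while members such as Spry4 and Etv4 were low together in clones 19 and 26. The p-values of this list and of the others can thus overstate the evidence. In the Wnt target list 2 of 7 members, Sp5 and Cdx1, were variable (3 adjusted over the list alone; exact test, adjusted p = 0.199994), while Axin2 (51.1 ± 10.1), Tcf7 (48.5 ± 10.6) and Znrf3 (30.9 ± 4.15 CPM) were not.

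Imprinted genes, which are read from 1 parental allele, formed the list with the lowest enrichment p. Grb10, which encodes an adaptor protein of insulin signalling, ranged from 29.6 CPM in clone 19 and 39.3 in clone 17 to 413 in clone 24 and 414 in clone 16. The amino acid transporter gene Slc38a4 ranged from 201 CPM in clone 16 to 969 in clone 17, Zdbf2 from 149 to 422 and Peg3 from 56.2 to 203. Directions differed between members: clone 24 held the lowest Plagl1 level and the highest Peg3 level of the 11 clones. Impact (445 ± 104 CPM) and Igf2r (442 ± 88.8) did not pass. Of 24 tested members 13 were variable (15 adjusted over the list alone), 54.2% against 7.60% of other genes (Fisher's exact test, adjusted p = 7.78e-08; 2.07e-08 to 6.86e-06 over 15 alternatives). Only 1 of the 13, and 1 of all 24 tested, lay in a shifted segment.

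**Figure D1:**
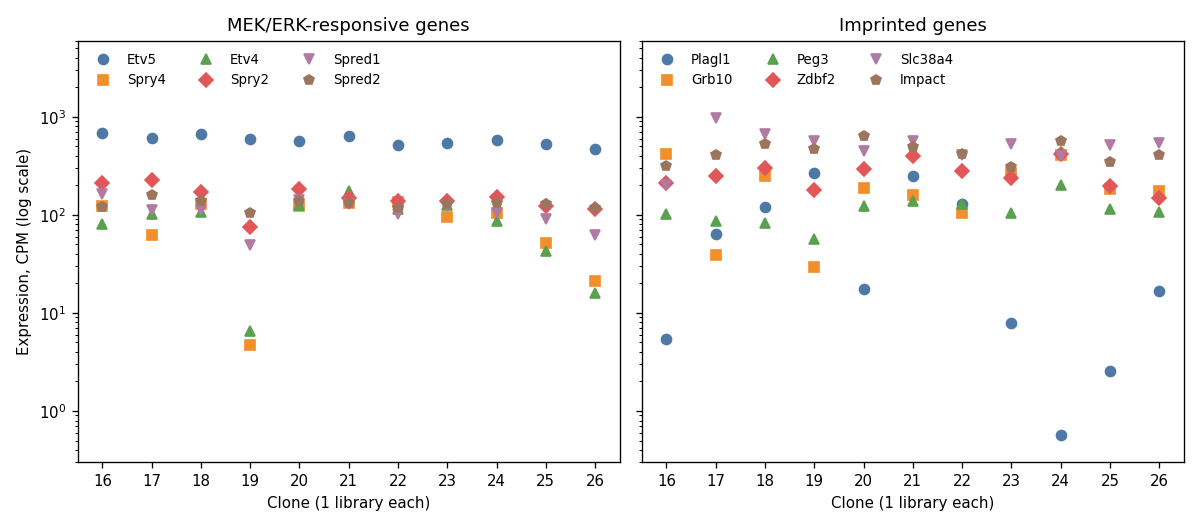
Level of 6 MEK/ERK-responsive and 6 imprinted genes in each clone, in CPM on a log axis, with 1 point per gene and library. Spry4 and Etv4 are lowest in clone 19 (4.68 and 6.58 CPM), next lowest in clone 26 (21.4 and 16.02), and Plagl1 runs from 0.567 to 267 CPM.

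Lineage lists with scattered members followed. In the primed epiblast list Otx2, a transcription factor gene of the primed state, was at 12.2 to 15.3 CPM in clones 16, 17 and 19 and at 28.1 to 54.9 in the others, and Zic2, which lies in a shifted part of chromosome 14, ranged from 15.4 to 93.0 CPM. Sox3 and Sox4 were also variable, while Dnmt3b (118 ± 14.997), Dnmt3a (105 ± 20.3) and Nodal (103 ± 13.5) were not. The list had 4 variable genes of 11 tested (6 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0218, range over 15 alternatives 0.00214 to 0.279). The call was lost at a mean CPM of at least 5 (p = 0.279) and without segment genes (p = 0.0517). In the primitive endoderm list 5 of 11 were variable (5 adjusted over the list alone; adjusted p = 0.00476, range 0.000333 to 0.171): the matrix genes Sparc (157 to 472 CPM), Lama1 (128 to 323) and Col4a1 (6.44 to 48.9), Col4a2 (3.71 to 34.2) and the activin antagonist Fst (9.99 to 30.6). This call was lost without clone 19 (p = 0.0723), without clone 20 (p = 0.0903), with no filter (p = 0.0510) and without segment genes (p = 0.171). In the trophoblast list 1 of 6, the keratin gene Krt8, was variable (3 adjusted over the list alone; adjusted p = 0.609), at 8.45 to 34.6 CPM, and Tfap2c (48.2 ± 13.2) was not. Krt8 lies in a segment shifted in at least 1 clone, as do 3 of all 6 tested members.

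The 2-cell-like list, named for the embryonic stage at which these genes are active, was low but uneven. Zscan4d ranged from 0.238 CPM in clone 17 to 6.44 in clone 26, Zscan4c from 0.159 to 5.32 and Tmem92 from 0.476 to 8.74. These 3 of 6 tested members were variable (4 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0218, range over 14 alternatives 0.000762 to 0.148), a call lost without clone 21 (p = 0.148) or clone 26 (p = 0.128). Zscan4c and Zscan4d are near-identical copies, and how reads shared between copies were counted is not given in the sources used here. In the germline list Dazl, an RNA-binding protein gene of germ cells, was at 112 CPM in clone 21 against 19.9 to 53.9 in the others. Sohlh2 ranged from 10.0 to 79.6, Stk31 from 15.2 to 49.9 and Hormad1 from 8.45 to 29.6 CPM, while Tex19.1 (42.2 ± 6.94) did not pass. With 4 of 13 members variable (5 adjusted over the list alone) the adjusted p was 0.0325, with a range over 15 alternatives from 0.00336 to 0.461. The call was lost without clone 21 (p = 0.461), clone 24 (p = 0.119) or segment genes (p = 0.149).

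Stress and metabolic lists also held variable members. Among p53 targets, Trp53inp1 was at 448 and 412 CPM in clones 26 and 24 against 177 to 306 elsewhere. Ccng1 stood at 427 and 403 against 144 to 290, and Zmat3 at 187 and 201 against 78.5 to 142. Cdkn1a, the cyclin-dependent kinase inhibitor, ranged from 40.4 to 127 CPM. Of 21 tested members 6 were variable (9 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0155, range over 15 alternatives 4.34e-05 to 0.152), a call lost without clone 24 (p = 0.130) or clone 26 (p = 0.152). Of 19 glycolysis and hypoxia genes 6 were variable (6 adjusted over the list alone; adjusted p = 0.0106, range 0.00184 to 0.298): Ldha, the lactate dehydrogenase, ran from 233 CPM in clone 25 to 686 in clone 17, Tpi1 from 166 to 385, Pfkl from 145 to 394 and Pdk1 from 57.4 in clone 19 to 302 in clone 20. That call was lost without clone 17 (p = 0.275), 25 (p = 0.298) or 26 (p = 0.291), and Pkm (2706 ± 433), Aldoa (1796 ± 401) and Pfkp (650 ± 85.9) did not pass. Of 12 heat shock and stress genes 4 were variable (4 adjusted over the list alone; adjusted p = 0.0266, range 0.0191 to 0.0604, the highest without segment genes): Chac1 (54.2 to 247 CPM), Trib3 (76.1 to 218), Herpud1 (38.9 to 137) and Atf3 (4.37 to 33.5), genes of the unfolded protein and amino acid responses, while Asns, Hspa5 and Hspa8 did not pass.

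Apart from the Y-linked list, treated with its chromosome, the remaining lists had no enrichment call. In the core and naive list 2 of 22 were variable (2 adjusted over the list alone; Fisher's exact test, adjusted p = 0.875): Dppa3, at 23.3 CPM in clone 19 and 0.136 to 5.18 elsewhere, and Utf1, at 76.6 to 239 CPM. The LIF/STAT3 target list had 0 of 10 variable (0 adjusted over the list alone), with 2 at an unadjusted p under 0.05 and 1 with the DESeq2 dispersion trend. Tbx3 stood at 707 ± 105 and Klf4 at 435 ± 89.7 CPM. Polycomb genes had 0 of 15 (0 adjusted over the list alone, 1 unadjusted, 0 with the DESeq2 trend), with Jarid2 at 708 ± 126, Phc1 at 559 ± 118 and Suz12 at 495 ± 50.9 CPM. Ribosomal protein genes (0 of 20) and housekeeping genes (0 of 10) had 0 calls in the edgeR test, adjusted over the list alone, unadjusted and with the DESeq2 trend. Rpl8 stood at 2591 ± 498, Rps3 at 1998 ± 170, Rpl13a at 1413 ± 189, Actb at 1005 ± 209 and Ywhaz at 577 ± 42.6 CPM. In the DNA methylation list Tet2 (308 to 1005 CPM) and Dnmt3l (154 in clone 19 to 638) were variable, 2 of 9 (3 adjusted over the list alone; adjusted p = 0.284), while Tet1 (1061 ± 161), Uhrf1 (677 ± 117) and Dnmt1 (528 ± 63.9) were not. Other lists held single variable members. These were Atrx (293 to 695 CPM) in the heterochromatin and lamina list (1 of 20; 1 adjusted over the list alone) and Ccne1 (25.9 to 78.8) in the cell cycle list (1 of 16; 2 adjusted over the list alone). Fdft1 (18.5 to 68.7) was the 1 of 17 in the cholesterol synthesis list (1 adjusted over the list alone). It lies in a segment shifted in at least 1 clone, as do 5 of all 17 tested members. Ddx58 (54.1 to 165) was the 1 of 5 in the interferon list (2 adjusted over the list alone). With Col1a1 as the 1 of 7 in the fibroblast list (4 adjusted over the list alone), these lists had adjusted p of 0.583 to 1 by the exact test.

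The second comparison set each clone against the other 10 and asked in which genes it stood apart. Clone 19 differed most, with the surface antigen gene Ly6a at 55.5 CPM against 1.68 ± 1.35 (SD, n = 10) in the others and Lrrc15 at 107 against 6.20 ± 4.42, and with lower Enox1 (10.6 against 78.2 ± 17.4), Klf12 (8.89 against 55.4 ± 14.1) and Adam23 (21.7 against 114 ± 24.1). Ly6a and Enox1 lie in segments of chromosomes 15 and 14 that were higher as a whole in clone 19, so Enox1 ran against its segment. In clone 16 the transcription factor gene Sox21 was at 133 CPM against 22.5 ± 5.32, a log2 fold change of 2.56 ± 0.26 (SE; edgeR quasi-likelihood test, adjusted p = 0.00329). Mycl, a Myc family gene, stood at 115 against 27.9 ± 5.24 (2.05 ± 0.22, adjusted p = 0.00341 by edgeR). The Ras family gene Mras was lower (-2.15 ± 0.36), as were Wfdc2 (-2.12 ± 0.30) and Srcin1. In clone 17 Limch1 (2.48 ± 0.41), Med12l (2.39 ± 0.42) and Atl1 (1.68 ± 0.21) were higher, and the zinc transporter gene Slc30a4 (-3.08 ± 0.46), the cell adhesion gene Ncam1 (-1.99 ± 0.34) and Lrch2 (-1.84 ± 0.19) lower. Over all 137269 gene and clone pairs, 293 passed at an adjusted p of 0.05, 144 higher and 149 lower, and 200 of them lay in a segment that was shifted as a whole in the same clone. Each call says that 1 library lies outside the spread of the other 10, with no second library of that clone behind it. The count fell to 183 without clone 18, 195 without clone 19, 160 without clone 20, 152 without clone 21, 183 without clone 22, 154 without clone 23 and 163 without clone 25. A clone left out takes its own calls with it. Of the 293, these were 112 for clone 19 but only 1 for clone 18. The count was 1434 (666 higher, 768 lower) with the DESeq2 Wald test, and 34 with genes in segments and Y-linked genes left out. In that last run the calls on Mras and Srcin1 in clone 16, Slc30a4, Cbx2, Limch1 and Ncam1 in clone 17, Adam23 in clone 19, 3222401L13Rik in clone 23, Sycp3 in clone 24 and Pmel and Stat2 in clone 26 were lost. Ly6a, Enox1, Sox21, Med12l, Klf12 and Fbxo25, among others, were not tested in it, since they lie in segments of some clone.

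Calls were unevenly spread over the clones. Most calls of clones 16, 17, 19 and 21 lay in segments shifted as a whole in the same clone. So did all calls of clone 22, on chromosome 8, and of clone 25, on chromosome 17, including Eif2ak2, Prkd3 and Dhx57 below. Clone 19 had 112 (28 higher, 84 lower), clone 17 had 64, clone 16 had 33 and clone 21 had 28 (1 higher, 27 lower). Clone 22 had 18 higher and 0 lower, among them Mmp2, a matrix metalloproteinase gene (30.3 CPM against 8.44 ± 1.76; SD, n = 10), Syce2 (63.3 against 29.2 ± 2.39) and Ciapin1 (145 against 78.5 ± 8.13), all within its chromosome 8 segment. In it, 176 genes were lower at an unadjusted p under 0.05 and 13 by DESeq2. Clone 25 had 17 lower and 0 higher, among them Eif2ak2, the double-stranded RNA-activated kinase (14.4 against 33.1 ± 2.96), Prkd3 (29.9 against 67.9 ± 6.51) and Dhx57 (26.4 against 59.6 ± 4.73), with 88 higher at an unadjusted p under 0.05 and 3 by DESeq2. In clone 21 Rnaseh2b, Oxa1l and Cdca2 were lower by 1.24 to 1.47 on the log2 scale, in its chromosome 14 segment. Clone 24 had 11 calls, with Nfkbiz (23.6 against 4.23 ± 0.780), Slc44a4 (49.7 against 16.7 ± 1.56) and the meiotic gene Sycp3 (27.8 against 7.87 ± 1.93) higher and the Y-linked Ddx3y, Eif2s3y and Uty lower. Clone 26 had 4, including Pmel at 172 against 27.0 ± 13.9995 CPM and Stat2 (log2 fold change 0.67 ± 0.11). Clone 20 had 3, including Slc35e4 at 35.4 against 4.28 ± 0.674 and Fbxo25. Clone 23 had 2, including 3222401L13Rik at 18.1 against 6.06 ± 0.978. Each of clones 20 and 23, the most alike of the 11, served in the reference of the other, and the count was 4 in clone 20 without clone 23 (1 on chromosome 1) and 1 in clone 23 without clone 20. Clone 18 had 1, ENSMUSG00000074140 at 43.1 against 1.35 ± 0.341.

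Preset lists held few of these calls. The Y-linked list had 3 of 5 tested genes called (5 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00285), and 2 of 5 without clone 24 (adjusted p = 0.0802). The imprinted list had 2 pairs, and the neural (Pax6 in clone 17), germline (Sycp3 in clone 24), polycomb (Cbx2, lower in clone 17), heterochromatin (Setdb1 in clone 16) and cell cycle (Ccna2 in clone 16) lists 1 each. Setdb1 and Ccna2 lie on chromosome 3, which was shifted as a whole in clone 16. The counts adjusted over the list alone were the same for these lists. For the MEK/ERK, LIF/STAT3, DNA methylation and interferon lists they were 3, 4, 3 and 1 against 0 over all pairs, with 11, 8, 9 and 5 pairs at an unadjusted p under 0.05 by edgeR and 4, 4, 3 and 3 by DESeq2.

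The third comparison asked whether genes of a whole chromosome were shifted together, since embryonic stem cell lines can gain or lose chromosomes in culture. In clone 16 the 463 genes of chromosome 3 had a median shift of 0.56 on the log2 scale, 1.47-fold, with 92.0% of them above the median of the clones. In clone 17 the 360 genes of chromosome 19 were higher by 0.54 (1.46-fold), and in clone 22 the 566 genes of chromosome 8 by 0.48 (1.39-fold). Chromosome 15 was higher in clones 16, 17 and 19 by 0.32, 0.25 and 0.33. Of 231 clone and chromosome pairs 11 were called, 8 higher and 3 lower, and 5 of these were on the Y chromosome. The 6 autosomal calls had p = 0.0001, the smallest that 10000 random gene sets can give (adjusted p = 0.00115, two-sided). Each held under 15 alternative runs with other scaling, pseudocounts, filters or a clone left out, at adjusted p of 0.00084 to 0.00154 by the same test. With a stricter threshold on the size of the shift, the call on chromosome 15 in clone 17 (0.25) was lost.

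**Figure D2:**
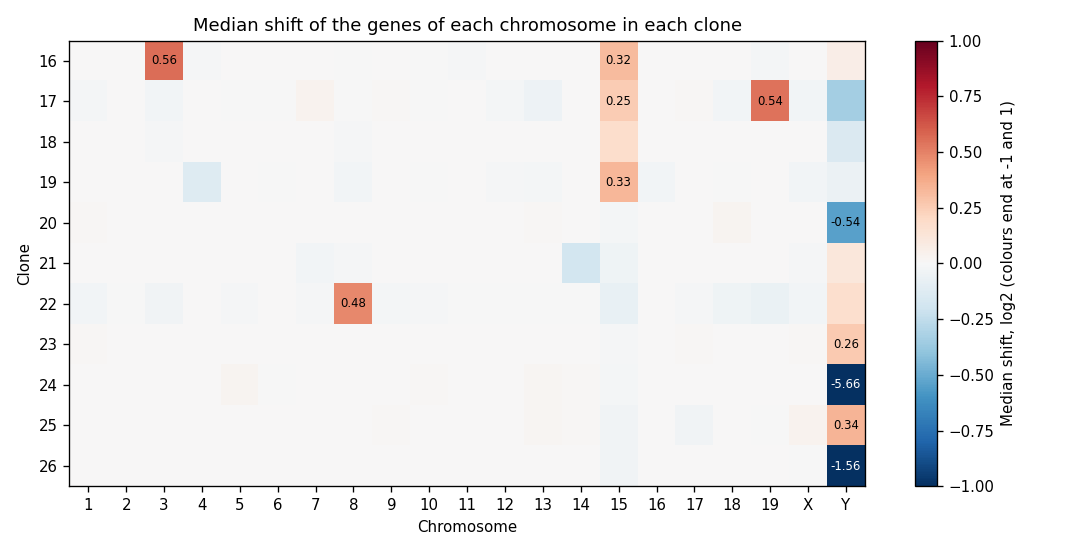
Median shift on the log2 scale of the genes of each chromosome (columns) in each clone (rows), against the median of each gene over the 11 clones, with the value printed where the pair was called. Chromosome 3 in clone 16 (0.56), 19 in clone 17 (0.54) and 8 in clone 22 (0.48) stand out, with chromosome 15 in clones 16, 17 and 19; the Y chromosome column rests on 5 genes.

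A scan of 25 neighbouring genes at a time, added after the chromosome-wide values had been seen, placed shifts on parts of chromosomes. It found 19 segments, 12 higher and 7 lower, in 9 clones. The genes that bound them were chosen by the scan, not by the rule for named genes. On chromosome 4 the 233 genes from Eya3 to Plekhn1 were lower in clone 19 by a median of -0.93 on the log2 scale (95% bootstrap interval over genes -0.98 to -0.89), 99.6% of them below the median of the clones. On chromosome 14 the 168 genes from Mettl17 to Mtrf1 were lower in clone 21 (-0.92, -0.95 to -0.89), and on chromosome 17 the last 57 genes, from Yipf4 to Mettl4, were lower in clone 25 (-0.84, -0.87 to -0.77). On chromosome 1 the same 90 genes, from Dsel to Kcnt2, were higher in clone 20 (0.52, 0.46 to 0.57) and clone 23 (0.49, 0.46 to 0.53). Near the end of chromosome 14, clones 16, 17 and 19 each had a higher stretch of 42 to 54 genes (0.77, 0.71 and 0.83) followed by a lower stretch of 19 to 25 genes (-1.13, -0.69 and -0.79), with ends that were in part shared. The higher stretch began at Polr3d in clones 17 and 19 and at Ccar2 in clone 16, and ended at a different gene in each. The lower stretch ran to Tmtc4, the last gene scanned on the chromosome, in clones 16 and 19, and to Ggact, its neighbour in the scan, in clone 17. Its start differed, at Abcc4, Gpc6 and Spry2 in clones 16, 17 and 19. On chromosome 15 the higher stretch began at Ly6a in clone 16, at Mroh4 in clones 17 and 19 and at Dmc1 in clone 18 (0.45 to 0.50 in these 4 clones). Clone 22 was higher over 545 genes of chromosome 8 from Arglu1 to Itgb1 (0.49). The weakest segment, 49 genes of chromosome 4 in clone 16, had a median of -0.21. Clones 24 and 26 had 0 segments, and their largest window shifts were -0.26 and -0.27 against a threshold of 0.36.

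**Figure D3:**
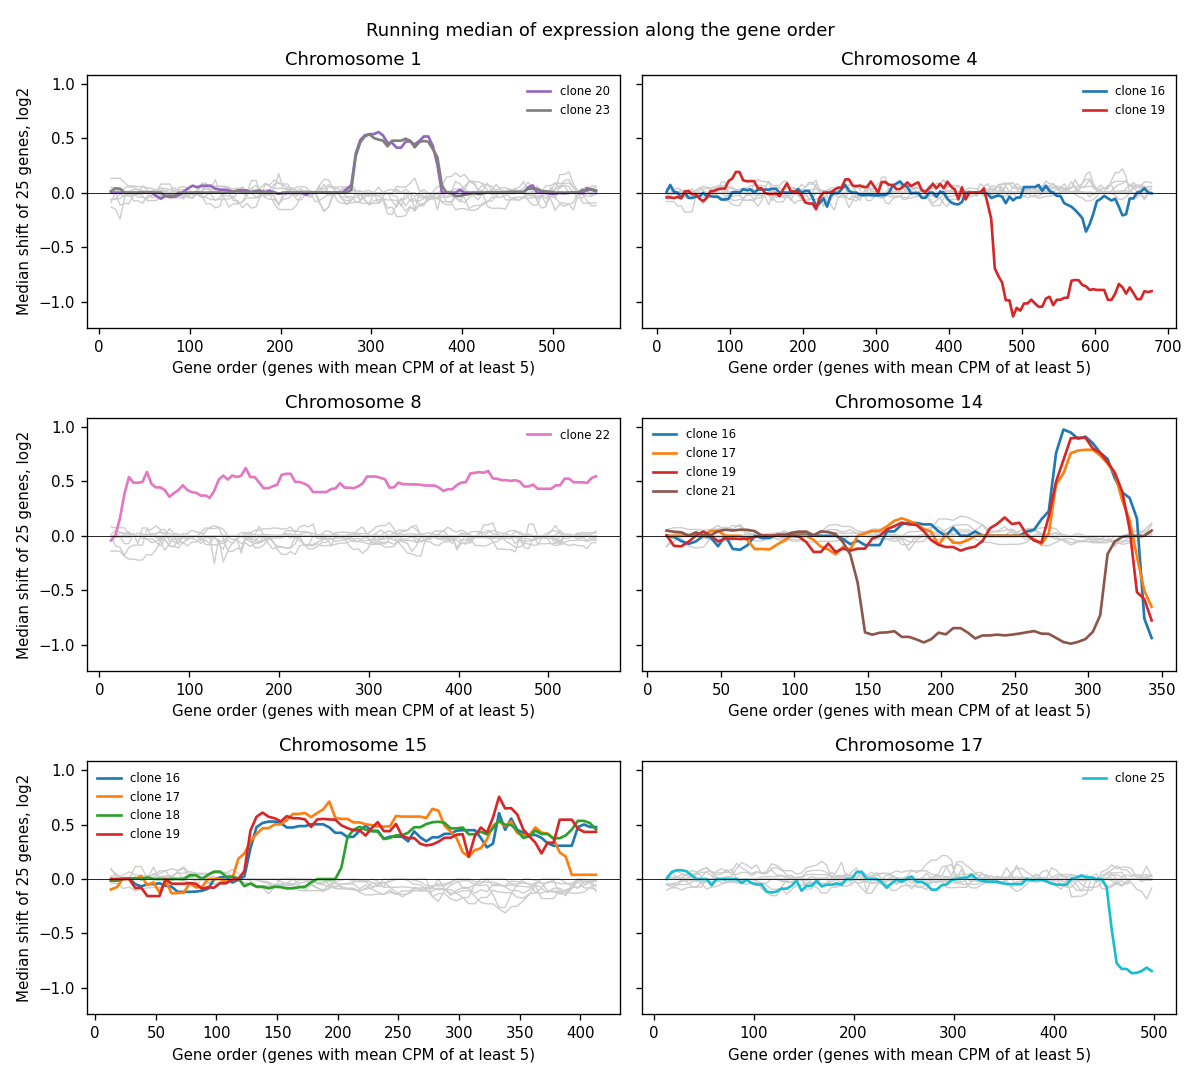
Running median over 25 neighbouring genes of the log2 shift from the median of the clones, against gene order, on 6 chromosomes; coloured lines are clones with a segment on that chromosome and grey lines the other clones. The lines of clones 20 and 23 rise over the same 90 genes of chromosome 1, and those of clones 19, 21 and 25 fall as low as -1.14, -0.99 and -0.86 on chromosomes 4, 14 and 17.

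Y-linked transcripts were nearly absent from clone 24. Summed over the 6 tested Y-linked genes, they came to 0.945 CPM in clone 24, 145 in clone 26, 289 in clone 20 and 322 to 546 in the other 8 clones. In clone 24, 15 counts were seen where the mean of the other clones gives 6483, a ratio of 0.231% (95% exact Poisson interval 0.129% to 0.382%, counting error only). Ddx3y and Eif2s3y, a helicase and a translation factor gene, had 1 count each, Uty had 8 (0.740%, 0.319% to 1.46%), and Zfy1 had 0, which was below the floor of 0.189 CPM in that library. In clone 26, Ddx3y stood at 59.04, Eif2s3y at 18.1 and Uty at 16.9 CPM, each below the 9 clones other than clone 24. Uba1y, at 46.3 CPM, and Zfy1, at 3.92, lay within the range of those 9 clones (19.003 to 129.97 and 2.27 to 17.8). All 5 tested members of the Y-linked list were variable (5 adjusted over the list alone; Fisher's exact test, adjusted p = 2.04e-05). As a chromosome, Y was lower in clones 24 (-5.66, 95% bootstrap interval -7.38 to -2.93), 26 (-1.56, -2.49 to -0.08) and 20 (-0.54, -0.72 to 0.23) and higher in 25 (0.34, 0.15 to 1.08) and 23 (0.26, 0.19 to 0.37), over 5 genes. The interval for clone 20 held 0. The call in clone 23 was lost without clone 17 or 18 (shift 0.20) and without clone 24 or 26 (0.19), where the shift was under 0.2. The median of the 335 X-linked genes in clone 24 did not move (0.00). Several of these genes have a close X-linked copy, and how shared reads were counted is not given in the sources used here.

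**Figure D4:**
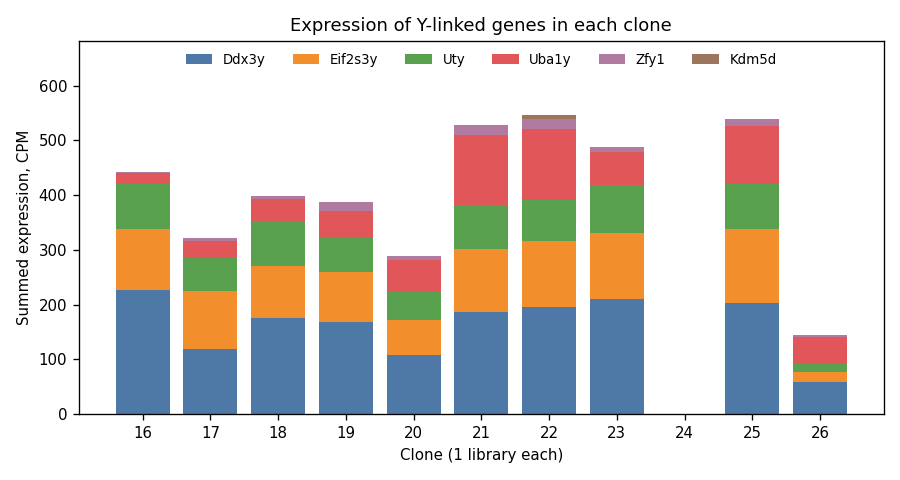
Expression of 6 Y-linked genes in each clone, in CPM, stacked per library. Clone 24 stands at 0.945 CPM and clone 26 at 145, against 289 to 546 in the other 9 clones.

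The last comparisons asked how alike the clones were and whether gene programmes moved together. Pearson's r across 12479 genes lay between 0.942 and 0.995 over the 55 pairs of clones. Genes are not independent replicates, so this describes the libraries only. Every pair differed by more than sampling noise, with a chi-square per degree of freedom from 4.72 to 68.8, and all 11 libraries were kept as separate samples. Clones 20 and 23 were the closest pair. Across the 11 clones, 0 of 6 preset pairs of list scores passed after Benjamini-Hochberg adjustment, by permutation tests with 100000 resamples. Of the 6, 1 had an unadjusted p under 0.05 by Pearson's r and 1 by Spearman's rho. Only strong links were simulated for this test, so a pair that did not pass can still be related. The naive and 2-cell-like scores had r = 0.62 (permutation p = 0.0444, adjusted 0.266) and rho = 0.50 (p = 0.122, adjusted 0.288), with r = 0.57 without the 2 clones farthest from the median. The DNA methylation and germline scores had r = 0.46 (p = 0.164, adjusted 0.329) and rho = 0.63 (permutation p = 0.0449, adjusted 0.269), with r = 0.60 without the 2 farthest. For the naive score with the primed epiblast, primitive endoderm and MEK/ERK scores r was -0.46, 0.20 and -0.18 (permutation p = 0.155, 0.560 and 0.603; adjusted 0.329, 0.603 and 0.603). Their rho was -0.47, 0.07 and -0.03 (p = 0.144, 0.838 and 0.945; adjusted 0.288, 0.945 and 0.945), and their r without the 2 farthest clones was -0.04, -0.28 and -0.38. The primed epiblast and MEK/ERK scores had r = 0.31 (permutation p = 0.356, adjusted 0.534) and rho = 0.34 (p = 0.312, adjusted 0.468), and r = 0.79 without clones 16 and 17.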

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

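The segment scan and the runs without segment and Y-linked genes were tests chosen only after the result was seen. Across the alternatives to each main result 82 values kept their size class and 17 moved. For counts of calls this class rests on the size of the count alone, without direction, and 0 against 0 was taken as the same. Among single results 553 were the same, 22 weaker and 3 reversed. Variable genes numbered 957 to 1328 under other settings and 873 to 919 without 1 clone, but 11902 against counting noise alone, by its construction, and 615 with segment and Y-linked genes left out. Pairs in which 1 clone stood apart numbered 257 to 295 under other settings, 152 to 278 without 1 clone, 1434 with the DESeq2 Wald test (291 shared) and 34 with segment and Y-linked genes left out. Each leave-one-out count also lacks the calls of the clone left out, 112 in the case of clone 19. The cause of the remaining leave-one-out differences and of the DESeq2 difference was not tested. Chromosome calls numbered 8 to 14, and windows of 25 genes gave 19 segments. Enriched lists among variable genes numbered 7 to 11, and 5 with segment genes left out. Among clone calls, enriched lists numbered 0 to 2 without 1 clone and 0 at a mean CPM of at least 5, where fewer Y-linked genes were tested. The correlation of the naive with the primitive endoderm score changed sign to -0.129 with a pseudocount of 0.1, and lay between -0.303 and 0.398 without 1 clone. That with the MEK/ERK score changed sign to 0.0539 with a pseudocount of 5. The cause was not tested, and neither passed a test in any setting. No paired analysis was possible because there is 1 group. At these depths 3 counts equalled 0.178 to 0.277 CPM, which limits Hprt, the Zscan4 genes and Y-linked genes in clone 24.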

Other observations

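Of the tests below, those of GC content and gene dosage were written before their results, and the tests on clones 20 and 23 and on clone 24 were chosen only after the result was seen. Some genes stood far from the other 10 clones in 1 clone, and those in this paragraph were chosen after their values were seen. Trp63, a p53 family transcription factor gene, stood at 40.0 CPM in clone 19 against a mean of 0.228 in the other 10 clones (edgeR, adjusted p = 0.000114). In the same clone Gpnmb was at 18.3 against 1.24 and Sox5 at 9.47 against 0.780, and the signalling gene Bmp4 was lower, at 9.01 against 44.7. The bile acid receptor gene Gpbar1 was at 29.0 CPM in clone 24 against 0.0553, the sterol transporter gene Npc1l1 at 28.9 in clone 20 against 0.591, and Fbxl22 at 36.2 in clone 26 against 0.277.

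The first pattern is the shift of whole chromosomes and of long runs of neighbouring genes in 1 to 4 clones. Bias from GC content or transcript length does not account for it, since shifts adjusted for both kept a median ratio of 0.998 to the unadjusted ones (0.909 to 1.08). Altered gene dosage may account for it: genes above and below the median expression of a segment differed by a median of only 0.0681 on the log2 scale (largest 0.257). Simulated 1.5-fold and 0.5-fold shifts read 0.48 and -0.88 by this measure, and the higher segments outside chromosome 14 had medians of 0.45 to 0.56 and the lower ones of clones 19, 21 and 25 on chromosomes 4, 14 and 17 of -0.93, -0.92 and -0.84, while the stretches near the end of chromosome 14 (0.71 to 0.83 and -0.69 to -1.13) and the chromosome 4 segment of clone 16 (-0.21) lay off these values. DNA copy number was not used here, the design names no biological group, and no biological explanation from it was tested.

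The second pattern is the likeness of clones 20 and 23, with r = 0.995 against 0.990 for the next pair and a correlation of deviations outside segments of 0.501 against 0.353. A single library deposited as 2 is excluded by a chi-square per degree of freedom of 4.72, and the next pair stood at 13.5. The same RNA prepared as 2 libraries is argued against by Npc1l1, at 28.9 CPM in clone 20 and 0.414 in clone 23, Slc35e4, at 35.4 and 3.73, and summed Ddx3y, Eif2s3y and Uty, at a ratio of 0.536 (0.513 to 0.561, counting error only, from 2711 and 7062 counts), all chosen after their values were seen, while Uba1y was alike (57.5 and 61.0). Descent from 1 cell that already carried the chromosome 1 segment may explain it, since the ends of that segment differed by 0 genes and 0 other clones had it. However, clones 17 and 19, the next pair by deviations, shared the starts Polr3d and Mroh4. Clones 16 and 19 shared the end Tmtc4, but that is the last gene scanned on chromosome 14. No biological explanation from the design was tested.

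The third pattern is the near absence of Y-linked transcripts in clone 24. Shallow sequencing is excluded, with 15 counts seen over 6 genes where 6483 were expected. A sample of another cell line with an active Hprt gene in its place is argued against by Hprt at 0.252 CPM (4 counts), within the 0 to 0.340 of the other clones. Loss of the Y chromosome was not tested, as DNA was not used here, and no biological explanation from the design was tested.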
